A study of Rattus norvegicus with 9 samples.

How the data were processed

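Alveolar macrophages of male Wistar rats were profiled by RNA sequencing after intratracheal nitrogen mustard (mechlorethamine, 0.125 mg/kg) or PBS. Per the labels' protocols, cells were collected by lung massage 1 d or 28 d after NM, RNA was purified with RNeasy columns, and paired end libraries were made with a TruSeq RNA kit. The time of the PBS collection, the strand of the libraries and the animals behind each library were not given in the sources used here. The 9 libraries fell into the 3 groups PBS, NM day 1 and NM day 28, each with replicates numbered 0, 1 and 2.

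Per the submitters' processing notes, reads were aligned with TopHat and quantified with Cuffdiff on the rat build rn4, and the versions, the annotation and the treatment of reads with several matches were not given in the sources used here. The authors deposited FPKM values per RefSeq transcript, 18197 transcript rows in each library, and these values were used here. A table of significant isoforms named in the labels was not analysed here. Gene symbols came from a RefSeq gene table of the assembly GRCr8, which named 17189 of the 18197 transcript rows (94.5%). No coordinates are printed, since the builds differ. There were 246 transcript rows with a locus suffix, 718 genes with several transcript rows, 1008 transcript rows without a symbol, and 73 transcript rows at 0 in 1 library and above 20 FPKM in another. Reads of near-identical genes (RT1, Klr and Ly6c families) may be shared.

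The FPKM of transcripts with the same symbol were summed, which gave 17109 genes, and 9885 genes with an FPKM of at least 1 in at least 3 of 9 libraries were tested, 576 of them without a symbol. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), with 3 group means and the spread shared over all 9 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. The addition of 1 makes fold changes of genes with low values smaller than the ratio of their FPKM. Errors are SD of FPKM within groups of 3 or the SE of the fitted log2 fold change. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

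Lists of genes were tested with camera, limma's competitive test, with the correlation between genes preset to 0.01 and adjustment over the lists of a comparison. The correlation was also estimated, and fry, a self-contained test, was run beside it. Of 32 lists 28 had at least 5 members tested. The biological lists were scavenger receptors and lipid uptake, cholesterol efflux and LXR targets, sterol biosynthesis, fatty acid oxidation, lipid droplets, esterification and lipolysis, fatty acid and phospholipid synthesis, pro-inflammatory activation, alternative activation and inflammation resolution, profibrotic factors and matrix remodelling, interferon-stimulated genes, p53 and DNA damage response, cross-link and homologous recombination repair, cell cycle and proliferation, NRF2 and oxidative stress response, lysosome, MHC class II antigen presentation, ER stress and integrated stress response, and glycolysis. The cell type lists were resident alveolar macrophage, monocyte and recruited macrophage, neutrophil, T cell, natural killer cell, dendritic cell, alveolar epithelium, airway epithelium, endothelium and erythroid. B cell, eosinophil and mast cell, fibroblast and smooth muscle, and platelet had too few members for a list test.

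The tests, lists, alternatives and the rule for the genes named were chosen before the data were examined. The rule named, for each comparison, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM (4 and 4 between the NM groups). It added up to 2 called genes with the smallest p from each list (biological lists only between the NM groups) and, whatever their values, Cd36, Msr1, Abca1, Abcg1, Nr1h3, Pparg, Cpt1a, Nos2 and Arg1. Some genes that the rule picks are not reported here. Other list members that the report names were chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalisation, isoforms tested singly, the replicate number as a factor, only the 6 libraries compared, robust eBayes, library weights and each library left out in turn. Where 1 library was left out, 2 stood for its group.

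Read counts were not used here, so relative depth was read from the most common ratio of FPKM values under 1 between each library and NM day 1 replicate 0. As a check, the ratios of 28 of 28 pairs of the other libraries lay within 0.1 on the log2 scale of those computed through that library (largest gap 0.00154). Upper quartiles of FPKM ran from 19.1 to 19.6. The test was tried on simulated data (200 genes changed, no rate for low FPKM). At log2 changes of 0.5, 1 and 2 it recovered 1.49%, 47.8% and 95.5% of genes for NM day 1 against PBS, 2.99%, 59.7% and 90.9% for NM day 28 against PBS, and 4.48%, 53.7% and 100% between the NM groups. False calls numbered 6, 5 and 8 of 9685 unchanged genes.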

Results

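RNA was sequenced from alveolar macrophages, the phagocytes of the lung's air spaces, of male Wistar rats given nitrogen mustard (NM) or phosphate-buffered saline (PBS) into the trachea. NM is an alkylating agent that cross-links DNA and injures the lung. The 9 libraries formed 3 groups of 3: PBS, 1 d after NM and 28 d after NM. The study's title names foam cells, macrophages filled with lipid, and their part in the lung fibrosis that follows NM. Absolute depth was not given, but the most common ratio of low FPKM values between libraries (transcripts taken to hold equally few fragments) gave relative depths between 1.42 and 2.58 for PBS, 1 and 1.47 for NM day 1 and 1.04 and 1.12 for NM day 28, with NM day 1 replicate 0 set to 1. Between 12112 and 12516 transcript rows lay above 0 in the PBS and NM day 1 libraries, against 11149 to 11339 in the NM day 28 libraries. Spearman's rho across the 9885 genes tested ran from 0.953 to 0.982 within groups and from 0.917 to 0.956 between them. Ferritin light chain (Ftl1) had the highest FPKM in each of the 9 libraries.

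**Figure D1:**
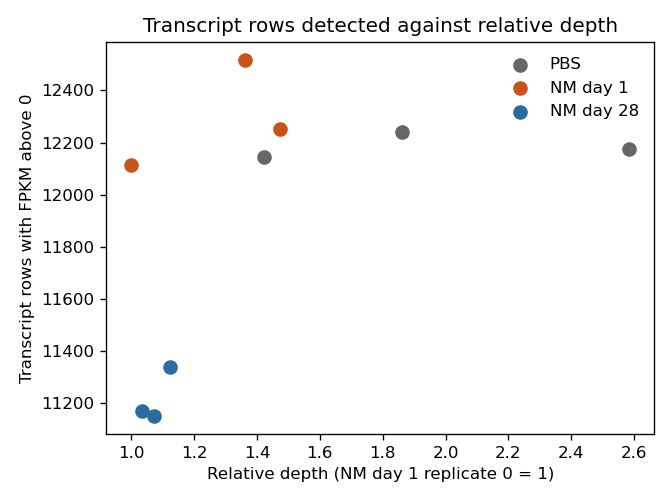
Number of transcript rows with an FPKM above 0 (vertical axis) against depth relative to NM day 1 replicate 0 (horizontal axis, a ratio without unit), 1 point per library, coloured by group. The NM day 28 libraries list 11149 to 11339 rows, and NM day 1 replicate 0, with a depth of 1 on this scale, lists 12112.

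The first comparison set NM day 1 against PBS. At day 1, 13 of 20 pro-inflammatory, 8 of 12 MHC class II and 11 of 16 alveolar epithelial list genes were higher than PBS. Of 17 cholesterol efflux and LXR genes 4 were lower, Abcg1 being the only exporter. Of the calls of these 4 lists the first was kept and the others lost (adjusted p = 0.0403, 0.0619, 0.0935 and 0.187 with an estimated correlation). Ccl12, a chemokine that attracts monocytes, rose from 0.108 ± 0.187 to 199 ± 25.8 FPKM (mean ± SD, n = 3; log2 fold change 7.50 ± 0.35 SE, adjusted p = 3.04e-07 by limma with Benjamini-Hochberg adjustment). The other largest rises were in Ccl7, S100a9, Slpi, Ccl17 and Ccl2, with log2 fold changes of 5.87, 5.81, 5.81, 5.66 and 5.61. The largest falls were smaller: Klk6 (-1.87), Tppp (-1.85), Tppp3 (-1.84), Pmepa1 (-1.48), Tnfrsf8 (-1.45) and Slc22a18 (-1.45). In all, 522 genes were higher and 453 lower of 9885 tested, and 394 of the former but 66 of the latter differed by more than 2-fold. Median-of-ratios scaling gave 542 higher and 338 lower, and quantile normalisation 459 and 307.

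Left out singly, most libraries moved these counts by over 1.5 times, as 2 libraries then stood for a group. Higher genes numbered 344 without PBS replicate 0, 306 without PBS replicate 1, and 181, 239 and 332 without NM day 1 replicate 0, 1 and 2. Lower genes numbered 215 and 80 without PBS replicate 0 and 1, 55, 176 and 251 without NM day 1 replicate 0, 1 and 2, and 721 without NM day 28 replicate 1, which shares the estimate of spread. Calls of Klk6 and Tppp3 ended in 1 or more of the fits without PBS replicate 0 or 1, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 2 (adjusted p up to 0.159, Klk6 without NM day 1 replicate 0). Klk6 did not pass with a pseudocount of 0.1 or without a filter or with isoforms tested singly or with robust eBayes (adjusted p up to 0.0926, Klk6 without a filter).

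Of 20 pro-inflammatory genes tested, 13 rose at day 1 (16 adjusted over the list alone; median log2 fold change 1.29). Camera put the pro-inflammatory activation list at adjusted p = 8.41e-13, and at adjusted p = 0.0403 with an estimated correlation. They included Nos2, the inducible nitric oxide synthase, at 13.04 ± 7.58 against 1.01 ± 0.685 FPKM (mean ± SD, n = 3; log2 fold change 2.68 ± 0.44 SE, adjusted p = 0.00313). The list of alternative activation and inflammation resolution had 9 members higher and 2 lower of 21 (12 and 2 adjusted over the list alone). Camera put the alternative activation and inflammation resolution list at adjusted p = 3.18e-07, and at adjusted p = 0.0348 with an estimated correlation. Ccl17 and Ccl22, ligands of Ccr4 on T cells, led it (5.66 and 4.60), and the members that fell were Tgfb1 (-0.80) and Klf4 (-0.82). Arginase 1 (Arg1) did not pass (169 ± 50.7 against 85.7 ± 45.0 FPKM, adjusted p = 0.0762), but passed without PBS replicate 0 (adjusted p = 0.0308) and after quantile normalisation (adjusted p = 0.0424). Markers of monocytes and recruited macrophages rose in 10 of 21 (10 adjusted over the list alone; camera adjusted p = 9.60e-11, adjusted p = 0.0348 with an estimated correlation), among them the integrin Itgam (3.45) and Plac8 (4.06). Calls of Klf4 and Tgfb1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2 or NM day 1 replicate 0, 1 or 2 (adjusted p up to 0.138, Tgfb1 without NM day 1 replicate 0). Klf4 did not pass without a filter or after quantile normalisation (adjusted p up to 0.0702, Klf4 after quantile normalisation).

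Of 11 neutrophil markers 5 rose at day 1, S100a8, S100a9, Cxcr2, Csf3r and Retnlg, and Cxcr1 fell (5 and 1 adjusted over the list alone). Camera put the neutrophil list at adjusted p = 0.000279, and at adjusted p = 0.0619 with an estimated correlation. S100a9, a subunit of calprotectin, went from 4.15 ± 1.97 to 292 ± 128 FPKM (SD, n = 3), and Retnlg was listed at 0 in every PBS library. Of 10 T cell markers 3 rose, Cd2 (2.20), Il7r (1.51) and Cd8a (1.39) (4 adjusted over the list alone). Camera put the T cell list at adjusted p = 0.00148, and at adjusted p = 0.0717 with an estimated correlation. Natural killer markers rose in 1 of 6, the receptor Klrk1 (4.13) (1 adjusted over the list alone). Camera put the natural killer cell list at adjusted p = 0.0256, and at adjusted p = 0.117 with an estimated correlation. Among dendritic cell markers 2 of 6 rose, Ccr7 (3.15) and Zbtb46 (1.13) (3 higher and 1 lower adjusted over the list alone), and the list did not pass. Camera put the dendritic cell list at adjusted p = 0.138, and at adjusted p = 0.264 with an estimated correlation. Blk (1.19) was the 1 of 3 B cell markers that rose (2 adjusted over the list alone; too few for a list test). The natural killer list missed the threshold without NM day 1 replicate 1 (adjusted p = 0.0606). The natural killer list also missed the threshold after quantile normalisation or with only the 6 libraries compared (adjusted p up to 0.147). Calls of Blk, Cd8a, Cxcr1 and Zbtb46 ended in 1 or more of the fits without PBS replicate 0, 1 or 2 or NM day 1 replicate 0, 1 or 2 (adjusted p up to 0.165, Zbtb46 without NM day 1 replicate 1). Blk, Cd8a and Zbtb46 did not pass with a pseudocount of 0.1, Blk, Cxcr1 and Zbtb46 after quantile normalisation, Cd8a without a filter, Zbtb46 with isoforms tested singly (adjusted p up to 0.107, Blk after quantile normalisation).

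MHC class II genes, whose products present peptides to helper T cells, rose in 8 of 12 members at day 1 (8 adjusted over the list alone; median log2 fold change 2.17). Camera put the MHC class II antigen presentation list at adjusted p = 2.24e-09, and at adjusted p = 0.0619 with an estimated correlation. RT1-Da went from 12.8 ± 1.92 to 293 ± 52.9 FPKM and RT1-Ba from 8.71 ± 1.74 to 201 ± 11.5 FPKM (mean ± SD, n = 3; adjusted p = 4.16e-06 and 1.68e-05 by limma). Reads may be shared among near-identical RT1 genes, but neither RT1-Da nor RT1-Ba had transcript rows at several loci. Interferon-stimulated genes rose in 10 of 26 (13 adjusted over the list alone; camera adjusted p = 1.40e-08, adjusted p = 0.0619 with an estimated correlation), among them Mx2 (3.52) and Irf7 (2.01). In the same libraries 11 of 16 alveolar epithelial markers rose (12 adjusted over the list alone, with 1 lower; median log2 fold change 1.74). Camera put the alveolar epithelium list at adjusted p = 2.24e-09, and at adjusted p = 0.0935 with an estimated correlation. The surfactant protein genes Sftpb and Sftpc, made by type II epithelial cells, reached 139 ± 94.1 and 1226 ± 882 FPKM, from 3.81 ± 1.10 and 46.1 ± 28.6. Airway epithelial markers fell in 1 of 9, Tppp3 (-1.84) (1 adjusted over the list alone). Camera put the airway epithelium list at adjusted p = 0.41, and at adjusted p = 0.731 with an estimated correlation. Of 6 endothelial markers Plvap (2.09) rose (1 higher and 1 lower adjusted over the list alone). Camera put the endothelium list at adjusted p = 0.259, and at adjusted p = 0.38 with an estimated correlation. Without NM day 1 replicate 0, the call of Tppp3 ended (adjusted p up to 0.0585).

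**Figure D2:**
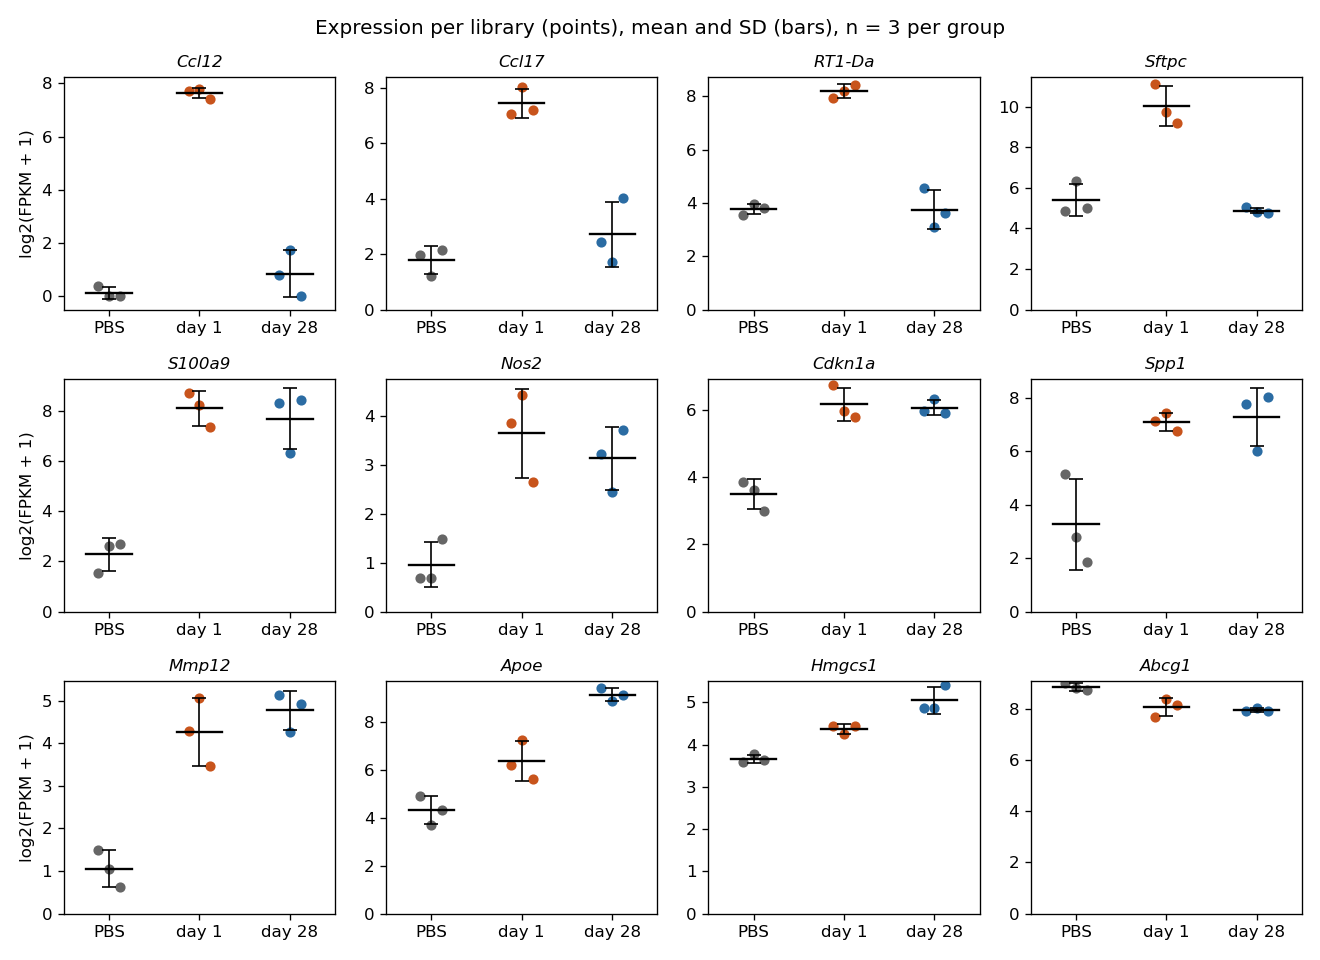
Expression of 12 genes as log2(FPKM + 1) (vertical axes) in PBS, NM day 1 and NM day 28 libraries. Points are single libraries, horizontal bars group means and whiskers 1 SD (n = 3). Ccl12, Ccl17, RT1-Da and Sftpc are highest at day 1, while Apoe is highest at day 28 (566 FPKM against 19.96 in PBS).

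Of 17 genes of cholesterol efflux and LXR targets, 4 fell at day 1, Nr1h2 (-0.98), Abcg1 (-0.77), Srebf1 (-0.70) and Nr1h3 (-0.73) (9 adjusted over the list alone). Camera put the cholesterol efflux and LXR targets list at adjusted p = 0.00148, and at adjusted p = 0.187 with an estimated correlation. Nr1h2 and Nr1h3 encode the LXR oxysterol receptors and Abcg1 a cholesterol exporter. Apoe, the apolipoprotein that carries exported cholesterol, was the 1 that rose, from 19.96 ± 8.34 to 90.3 ± 53.7 FPKM (SD, n = 3; log2 fold change 2.04 ± 0.37 SE, adjusted p = 0.00585 by limma). Abca1, the other main exporter, did not pass (56.8 ± 33.8 against 102 ± 27.8 FPKM, adjusted p = 0.108; 0.0205 without NM day 1 replicate 1). Of 14 scavenger receptors and lipid uptake genes limma called 0, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Camera put the scavenger receptors and lipid uptake list at adjusted p = 0.24, and at adjusted p = 0.526 with an estimated correlation. Cd36 and Msr1, receptors for modified lipoproteins, had log2 fold changes of -0.03 ± 0.36 and 0.09 ± 0.16 (SE; adjusted p = 0.974 and 0.775). Calls of Abcg1, Nr1h3 and Srebf1 ended in 1 or more of the fits without PBS replicate 0 or 1 or NM day 1 replicate 0, 1 or 2 (adjusted p up to 0.152, Srebf1 without NM day 1 replicate 0). Abcg1, Nr1h3 and Srebf1 did not pass after quantile normalisation, Apoe, Nr1h3 and Srebf1 with isoforms tested singly, Nr1h3 without a filter or after median-of-ratios scaling (adjusted p up to 0.124, Abcg1 after quantile normalisation).

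Sterol biosynthesis genes rose in 2 of 22 at day 1, Idi1 (1.12) and Hmgcs1 (0.71) (2 adjusted over the list alone). Camera put the sterol biosynthesis list at adjusted p = 0.0256, and at adjusted p = 0.268 with an estimated correlation. Fatty acid oxidation genes fell in 4 of 21, Acadvl (-0.73), Ech1 (-0.76), Eci1 (-0.76) and Acads (-0.83) (4 adjusted over the list alone). Camera put the fatty acid oxidation list at adjusted p = 0.00782, and at adjusted p = 0.296 with an estimated correlation. Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of -0.09 ± 0.16 (SE, adjusted p = 0.767). In the list of lipid droplets, esterification and lipolysis, Cidec (-1.004) and Mgll (-0.66) fell and Acsl4 (0.73) rose of 21 (4 lower and 1 higher adjusted over the list alone). Camera put the lipid droplets, esterification and lipolysis list at adjusted p = 0.0978, and at adjusted p = 0.187 with an estimated correlation. Cidec coats lipid droplets and Mgll cleaves monoacylglycerol. In fatty acid and phospholipid synthesis 2 of 16 rose, Pla2g7 (3.86) and Chka (0.70), and Pla2g15 (-1.02) fell (3 and 2 adjusted over the list alone). Camera put the fatty acid and phospholipid synthesis list at adjusted p = 0.416, and at adjusted p = 0.491 with an estimated correlation. Among lysosome genes Ctsl (1.75) rose and Tfeb (-1.11), Hexa (-1.02), Lamp1 (-0.93), Tpp1 (-0.64) and Man2b1 (-0.54) fell of 26 (2 and 7 adjusted over the list alone). Camera put the lysosome list at adjusted p = 0.0978, and at adjusted p = 0.638 with an estimated correlation. The sterol list missed the threshold without PBS replicate 0 or 2 or NM day 1 replicate 2 (adjusted p up to 0.0816), and the oxidation list without PBS replicate 0 (0.0681). The sterol list also missed the threshold with fry (adjusted p = 0.0697) and the oxidation list after quantile normalisation (0.0722). Calls of Acads, Acadvl, Acsl4, Chka, Ech1, Eci1, Hexa, Hmgcs1, Idi1, Lamp1, Man2b1, Mgll, Pla2g15, Tfeb and Tpp1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 or 2 (adjusted p up to 0.227, Tpp1 without NM day 1 replicate 0). Acads, Eci1, Man2b1, Mgll and Tpp1 did not pass after quantile normalisation, Acads, Lamp1 and Tpp1 without a filter, Cidec, Man2b1 and Tpp1 with isoforms tested singly, Man2b1 and Tpp1 with a pseudocount of 0.1 or with a pseudocount of 5 or with a filter of 5 FPKM or after median-of-ratios scaling or with only the 6 libraries compared or with robust eBayes (adjusted p up to 0.294, Cidec with isoforms tested singly).

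Some genes of matrix remodelling, DNA damage and cell division rose at day 1, while most members of these lists did not pass. Profibrotic factors rose in 8 of 20 (8 adjusted over the list alone, with 1 lower), including the matrix proteins Tgfbi (5.19) and Fn1 (2.38). Their list stood at adjusted p = 0.000245 by camera, and at adjusted p = 0.15 with an estimated correlation. Of 22 p53 and DNA damage genes 8 rose (10 adjusted over the list alone; camera adjusted p = 8.34e-06, adjusted p = 0.0736 with an estimated correlation), among them Cdkn1a, the p21 inhibitor of the cell cycle, at 73.1 ± 27.1 against 10.5 ± 3.27 FPKM (SD, n = 3), and Gadd45b (2.74). Cell cycle genes rose in 7 of 32 (9 adjusted over the list alone; camera adjusted p = 1.64e-06, adjusted p = 0.105 with an estimated correlation), including the replication licensing genes Mcm4 (1.21) and Mcm6 (1.19). In cross-link repair Palb2 (0.98) rose and Ercc1 (-0.66) fell of 13 (3 and 1 adjusted over the list alone). Camera put the cross-link and homologous recombination repair list at adjusted p = 0.0978, and at adjusted p = 0.187 with an estimated correlation. The oxidative stress list had 4 of 26 higher, Gpx2 (2.26), Slc7a11 (1.74), Nfe2l2 (0.73) and Gsta1 (1.31) (5 adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.491 with an estimated correlation), but not without PBS replicate 2 (adjusted p = 0.332). The oxidative stress list also missed the threshold with library weights or with fry (adjusted p up to 0.257). Tpi1 was the 1 of 17 glycolysis genes that rose (0.89; 1 adjusted over the list alone). Camera put the glycolysis list at adjusted p = 0.421, and at adjusted p = 0.731 with an estimated correlation. Limma called 0 of 20 ER stress genes, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Camera put the ER stress and integrated stress response list at adjusted p = 0.408, and at adjusted p = 0.731 with an estimated correlation. Calls of Ercc1, Gsta1, Mcm4, Mcm6, Nfe2l2, Palb2 and Tpi1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 2 (adjusted p up to 0.222, Gsta1 without NM day 1 replicate 0). Gsta1 and Palb2 did not pass after quantile normalisation, Gsta1 with a pseudocount of 5 or without a filter or with a filter of 5 FPKM or with isoforms tested singly (adjusted p up to 0.113, Gsta1 after quantile normalisation).

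Of 14 markers of resident alveolar macrophages, Cidec (-1.004), Abcg1 (-0.77) and Pparg (-0.57) fell and Car4 (3.33) rose at day 1 (3 and 1 adjusted over the list alone). Camera put the resident alveolar macrophage list at adjusted p = 0.138, and at adjusted p = 0.411 with an estimated correlation. Pparg, the lipid-sensing receptor that alveolar macrophages need to mature, went from 177 ± 2.78 to 120.1 ± 18.3 FPKM (SD, n = 3). Limma called 0 of 5 erythroid markers (2 at an unadjusted p under 0.05; 0 adjusted over the list alone). Camera put the erythroid list at adjusted p = 0.0748, and at adjusted p = 0.394 with an estimated correlation. Limma also called 0 of 2 eosinophil and mast cell, 2 fibroblast and smooth muscle and 4 platelet markers (0 at an unadjusted p under 0.05 and 0 adjusted over each list alone). Calls of Abcg1 and Pparg ended in 1 or more of the fits without PBS replicate 0, 1 or 2 or NM day 1 replicate 0, 1 or 2 (adjusted p up to 0.141, Pparg without NM day 1 replicate 0). Abcg1 and Pparg did not pass after quantile normalisation, Cidec and Pparg with isoforms tested singly (adjusted p up to 0.294, Cidec with isoforms tested singly).

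The second comparison set NM day 28 against PBS. With no PBS time given, neither comparison tells NM from time. At day 28 Apoe stood out: it rose from 19.96 ± 8.34 to 566 ± 103 FPKM (mean ± SD, n = 3; log2 fold change 4.82 ± 0.37 SE, adjusted p = 0.000175 by limma). S100a9 stayed far above PBS (5.41), and the proteoglycan Srgn, the macrophage growth factor Csf1, osteopontin (Spp1) and Ccl2 were higher by log2 4.15, 4.05, 4.01 and 3.95. The largest falls were in Itln1 (-4.04), Scgb3a1 (-3.67), Scgb3a2 (-3.14), Bpifb1 (-2.71) and Krt18 (-2.68). A RefSeq record without a gene symbol also fell, from 8.42 ± 7.15 FPKM in PBS, and was listed at 0 in the 3 day 28 libraries. In all, 303 genes were higher and 393 lower of 9885 tested, 189 and 180 of them by more than 2-fold. Median-of-ratios scaling gave 317 higher and 346 lower, and quantile normalisation 348 and 312, which turned the balance. Without PBS replicate 1, NM day 28 replicate 0 or NM day 28 replicate 2, higher genes numbered 154, 172 and 171. Without PBS replicate 0 or 1 or NM day 28 replicate 2, lower genes numbered 218, 120 and 217. Calls of Scgb3a1 and Scgb3a2 ended in 1 or more of the fits without PBS replicate 1 or 2, NM day 1 replicate 0 or NM day 28 replicate 1 or 2 (adjusted p up to 0.157, Scgb3a2 without PBS replicate 1). Scgb3a1 and Scgb3a2 did not pass without a filter or with robust eBayes, Scgb3a2 with a pseudocount of 0.1 or with isoforms tested singly or with only the 6 libraries compared (adjusted p up to 0.108, Scgb3a2 with robust eBayes). The call of the record without a symbol ended without PBS replicate 0 or 2 or any 1 NM day 28 library (adjusted p up to 0.112), and with a pseudocount of 5, without a filter, with isoforms tested singly or with robust eBayes (up to 0.0902).

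Sterol synthesis was the lipid group with the most members higher at day 28. Of 22 genes 8 rose (15 higher and 1 lower adjusted over the list alone; median log2 fold change 0.70). Camera put the sterol biosynthesis list at adjusted p = 1.13e-06, and at adjusted p = 0.286 with an estimated correlation. Hmgcs1, which makes the precursor of mevalonate, went from 11.7 ± 0.800 to 32.7 ± 7.69 FPKM (SD, n = 3; adjusted p = 0.00118), and Insig1 (1.00), a sterol sensor, also rose. In cholesterol efflux Apoe (4.82) and Pltp (0.88) rose and Abcg1 (-0.90) fell of 17 (2 and 2 adjusted over the list alone). The list's median was -0.18 but its mean 0.22, and its test pointed down. Camera put the cholesterol efflux and LXR targets list at adjusted p = 0.908, and at adjusted p = 0.949 with an estimated correlation. Of 14 scavenger receptors and lipid uptake genes Scarb1 (0.87) rose and Slc27a4 (-0.61) fell (2 and 3 adjusted over the list alone). Camera put the scavenger receptors and lipid uptake list at adjusted p = 0.628, and at adjusted p = 0.872 with an estimated correlation. Cd36 and Msr1 had log2 fold changes of -0.23 ± 0.36 and -0.36 ± 0.16 (SE; adjusted p = 0.746 and 0.202). None of Abca1 (-0.17, adjusted p = 0.816), Nr1h3 (-0.46, adjusted p = 0.18), Pparg (0.05, adjusted p = 0.893) and Cpt1a (-0.47, adjusted p = 0.0966) passed. Calls of Abcg1, Pltp, Scarb1 and Slc27a4 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.164, Pltp without PBS replicate 1). Pltp and Slc27a4 did not pass with only the 6 libraries compared, Abcg1 after quantile normalisation, Pltp without a filter or with isoforms tested singly (adjusted p up to 0.0932, Pltp without a filter).

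Fatty acid oxidation genes fell in 3 of 21 at day 28, Acads (-1.25), Ech1 (-0.82) and Cpt2 (-0.83) (3 adjusted over the list alone). Camera put the fatty acid oxidation list at adjusted p = 0.179, and at adjusted p = 0.67 with an estimated correlation. Of 21 genes of lipid droplets, esterification and lipolysis Cidec (-1.46) and Nceh1 (-1.08) fell (2 adjusted over the list alone; camera adjusted p = 0.168, adjusted p = 0.337 with an estimated correlation), Nceh1 being a hydrolase of cholesteryl esters. In fatty acid and phospholipid synthesis Pla2g7 (3.81) and Chka (1.07) rose and Pla2g15 (-0.82) fell of 16 (5 and 2 adjusted over the list alone). Camera put the fatty acid and phospholipid synthesis list at adjusted p = 0.168, and at adjusted p = 0.337 with an estimated correlation. Pla2g7, the phospholipase that hydrolyses platelet-activating factor and oxidised phospholipids, was at 24.2 ± 13.4 FPKM against 0.627 ± 0.489 in PBS (SD, n = 3). Of 26 lysosome genes 2 rose, among them the protease Ctsk (1.82) (4 higher and 2 lower adjusted over the list alone). Camera put the lysosome list at adjusted p = 0.455, and at adjusted p = 0.872 with an estimated correlation. Calls of Cpt2, Ech1, Nceh1 and Pla2g15 ended in 1 or more of the fits without PBS replicate 0 or 1, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.15, Nceh1 without PBS replicate 1). Cidec, Cpt2, Nceh1 and Pla2g15 did not pass with isoforms tested singly, Cpt2, Ech1, Nceh1 and Pla2g15 with only the 6 libraries compared, Cpt2, Nceh1 and Pla2g15 without a filter, Cpt2 and Pla2g15 after quantile normalisation (adjusted p up to 0.2, Cidec with isoforms tested singly).

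Some inflammatory and matrix genes were higher than in PBS at day 28, while most members of these lists did not pass. Pro-inflammatory genes rose in 7 of 20 (9 adjusted over the list alone; camera adjusted p = 1.04e-05, adjusted p = 0.286 with an estimated correlation), among them Cxcl2, a neutrophil attractant (3.05), and Nos2, at 8.30 ± 3.83 against 1.01 ± 0.685 FPKM (SD, n = 3; log2 fold change 2.17 ± 0.44 SE, adjusted p = 0.0126 by limma). Profibrotic factors rose in 7 of 20 (10 higher and 1 lower adjusted over the list alone). Camera put the profibrotic factors and matrix remodelling list at adjusted p = 7.02e-05, and at adjusted p = 0.286 with an estimated correlation. The members that rose included Fn1 (2.54) and Mmp12, the macrophage elastase, at 27.2 ± 8.15 against 1.14 ± 0.641 FPKM. In alternative activation Il1r2 (3.35), Chi3l1 (2.52), Il1rn (0.87) and Retnla (2.55) rose and Mrc1 (-0.73) fell of 21 (4 and 2 adjusted over the list alone; camera adjusted p = 0.138, adjusted p = 0.337 with an estimated correlation), and Arg1 had a log2 fold change of 0.74 ± 0.36 (SE, adjusted p = 0.234). Of 26 interferon-stimulated genes Ifit3 (2.00), Oasl (1.31) and Usp18 (0.74) rose and Bst2 (-2.38) fell (6 and 1 adjusted over the list alone). Camera put the interferon-stimulated genes list at adjusted p = 0.235, and at adjusted p = 0.668 with an estimated correlation. MHC class II genes fell in 1 of 12, RT1-DMa (-0.81) (3 adjusted over the list alone; camera adjusted p = 0.0054, adjusted p = 0.337 with an estimated correlation), and the list missed the threshold without NM day 28 replicate 1 (adjusted p = 0.212). The MHC class II list also missed the threshold with library weights or with fry (adjusted p up to 0.0717). Calls of Il1rn, Mrc1, Nos2, Oasl, RT1-DMa, Retnla and Usp18 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.13, Usp18 without PBS replicate 1). Chi3l1, Retnla and Usp18 did not pass with isoforms tested singly, Mrc1 and Retnla after quantile normalisation, Mrc1 and Usp18 with only the 6 libraries compared, Retnla and Usp18 without a filter, Retnla with a pseudocount of 5 or with robust eBayes (adjusted p up to 1, Chi3l1 with isoforms tested singly).

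The p53 and DNA damage list had 5 of 22 genes higher at day 28, Cdkn1a (2.57), Mdm2 (1.16), Ccng1 (0.85), Gdf15 (1.08) and Pmaip1 (1.97) (9 adjusted over the list alone). Camera put the p53 and DNA damage response list at adjusted p = 0.00122, and at adjusted p = 0.286 with an estimated correlation. Cdkn1a was at 66.2 ± 11.1 FPKM against 10.5 ± 3.27 in PBS (SD, n = 3). Cell cycle genes fell in 7 of 32, among them the proliferation marker Mki67 (-1.15), and Ccne2 (1.24) rose (11 and 1 adjusted over the list alone). Camera put the cell cycle and proliferation list at adjusted p = 0.00214, and at adjusted p = 0.337 with an estimated correlation. Oxidative stress genes rose in 7 of 26 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.471 with an estimated correlation), including Gclc (0.98), of glutathione synthesis. That list missed the threshold without PBS replicate 2 (adjusted p = 0.101). The oxidative stress list also missed the threshold with fry (adjusted p = 0.148). In the ER stress list Hsp90b1 (-1.08) and Hspa5 (-0.82) fell and Asns (0.80) rose of 20 (3 and 1 adjusted over the list alone). Camera put the ER stress and integrated stress response list at adjusted p = 0.628, and at adjusted p = 0.895 with an estimated correlation. Limma called 0 of 13 cross-link repair and 0 of 17 glycolysis genes, with 1 and 1 at an unadjusted p under 0.05 and 0 adjusted over each list alone (camera adjusted p = 0.628 and 0.716, adjusted p = 0.717 and 0.905 with an estimated correlation). Calls of Asns, Ccng1, Gdf15, Hspa5 and Pmaip1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.132, Gdf15 without PBS replicate 1). Asns, Gdf15, Hspa5 and Pmaip1 did not pass without a filter or with only the 6 libraries compared, Pmaip1 with isoforms tested singly (adjusted p up to 0.0765, Pmaip1 without a filter).

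Markers of other cells moved in both directions at day 28. Airway epithelial markers fell in 4 of 9, Krt15 (-2.18), Cyp2f4 (-1.80), Scgb3a1 (-3.67) and Scgb3a2 (-3.14) (7 adjusted over the list alone; median log2 fold change -1.80). Camera put the airway epithelium list at adjusted p = 7.02e-05, and at adjusted p = 0.337 with an estimated correlation. Of 16 alveolar epithelial markers Aqp5 (-2.36) and Krt18 (-2.68) fell and Hopx (1.19) rose (3 and 1 adjusted over the list alone), with a median of 0.18, a mean of -0.32 and a test that pointed down. Camera put the alveolar epithelium list at adjusted p = 0.597, and at adjusted p = 0.872 with an estimated correlation. Neutrophil markers rose in 4 of 11, S100a9 (5.41), S100a8 (3.49), Cxcr2 (2.10) and Csf3r (1.73) (5 adjusted over the list alone). Camera put the neutrophil list at adjusted p = 0.00838, and at adjusted p = 0.286 with an estimated correlation. Monocyte markers rose in 3 of 21, among them Itgam (2.75), and Fcgr3a (-1.30) fell (3 and 1 adjusted over the list alone). Camera put the monocyte and recruited macrophage list at adjusted p = 0.138, and at adjusted p = 0.46 with an estimated correlation. Resident macrophage markers Cidec (-1.46), Abcg1 (-0.90) and Mrc1 (-0.73) fell and Car4 (2.46) rose of 14 (3 and 1 adjusted over the list alone). Camera put the resident alveolar macrophage list at adjusted p = 0.235, and at adjusted p = 0.62 with an estimated correlation. Of 6 endothelial markers Tie1 (2.20) rose and Esam (-1.80) fell (1 and 3 adjusted over the list alone). Camera put the endothelium list at adjusted p = 0.231, and at adjusted p = 0.405 with an estimated correlation. Calls of Abcg1, Csf3r, Fcgr3a, Hopx, Mrc1, Scgb3a1 and Scgb3a2 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.157, Scgb3a2 without PBS replicate 1). Csf3r, Hopx, Scgb3a1 and Scgb3a2 did not pass without a filter, Csf3r, Hopx, Mrc1 and Scgb3a2 with only the 6 libraries compared, Cidec, Hopx and Scgb3a2 with isoforms tested singly, Abcg1 and Mrc1 after quantile normalisation, Scgb3a1 and Scgb3a2 with robust eBayes, Car4 with a pseudocount of 5, Scgb3a2 with a pseudocount of 0.1 (adjusted p up to 0.2, Cidec with isoforms tested singly).

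Of lymphocyte and dendritic cell markers at day 28, Ncr1 (1.37, to 1.68 FPKM) rose and Ncr3 (-0.62), Fcrla (-1.55, 443 FPKM in PBS) and Cd1d1 (-0.97) fell. The natural killer list (2 higher and 2 lower of 6 adjusted over the list alone) had a median of -0.13, a mean of 0.09 and an upward test. Camera put the natural killer cell list at adjusted p = 0.908, and at adjusted p = 0.932 with an estimated correlation. The dendritic cell list (2 lower of 6 adjusted over the list alone) had a median of 0.10, a mean of -0.16 and a downward test. Camera put the dendritic cell list at adjusted p = 0.732, and at adjusted p = 0.872 with an estimated correlation. Fcrla was the 1 of 3 B cell markers called (1 adjusted over the list alone). Limma called 0 of 10 T cell and 0 of 5 erythroid markers, with 3 and 1 at an unadjusted p under 0.05 and 0 adjusted over each list alone (camera adjusted p = 0.716 and 0.0892, adjusted p = 0.872 and 0.471 with an estimated correlation). It also called 0 of 2 eosinophil and mast cell, 2 fibroblast and smooth muscle and 4 platelet markers, with 1, 0 and 2 at an unadjusted p under 0.05, and 1 lower, 0 and 1 higher adjusted over each list alone. Calls of Cd1d1, Fcrla, Ncr1 and Ncr3 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.151, Fcrla without PBS replicate 1). Cd1d1, Fcrla and Ncr3 did not pass without a filter or with isoforms tested singly or with only the 6 libraries compared, Fcrla and Ncr3 after quantile normalisation, Fcrla with robust eBayes, Ncr3 after median-of-ratios scaling (adjusted p up to 0.103, Fcrla without a filter).

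The third comparison set NM day 28 against NM day 1 and tested which responses differed between the times. Most MHC class II (10 of 12), cell cycle (18 of 32) and alveolar epithelial (12 of 16) list genes were lower at day 28. Higher were 5 of 17 cholesterol efflux and LXR target genes and 5 of 22 sterol synthesis genes. All 15 list calls of this comparison were lost with an estimated correlation (lowest adjusted p = 0.0659 with an estimated correlation). The largest rises were in Trem2 (2.85), Apoe (2.78), Gcgr (2.33) and Enpp1 (2.25), Trem2 being a lipid-sensing receptor of macrophages that went from 67.2 ± 61.9 to 409 ± 218 FPKM (mean ± SD, n = 3; PBS 146 ± 108; log2 fold change 2.85 ± 0.75 SE, adjusted p = 0.03 by limma). The largest falls were in Ccl12 (-6.78), Sftpc (-5.15), Hist1h2ail1 (-5.04) and RT1-Ba (-4.87). In all, 470 genes were higher and 680 lower at day 28 of 9885 tested, 130 and 499 of them by more than 2-fold. Median-of-ratios scaling gave 422 higher and 702 lower, and quantile normalisation 584 and 603. Without NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 or 2, higher genes numbered 252, 214, 274, 226 and 267. Without NM day 1 replicate 0, 1 or 2, lower genes numbered 324, 300 and 384. Calls of Hist1h2ail1 and Trem2 ended in 1 or more of the fits without PBS replicate 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 or 2 (adjusted p up to 0.149, Hist1h2ail1 without NM day 1 replicate 1). Apoe, Hist1h2ail1 and Trem2 did not pass with isoforms tested singly, Hist1h2ail1 and Trem2 without a filter or with robust eBayes, Hist1h2ail1 with a pseudocount of 0.1 or with only the 6 libraries compared (adjusted p up to 0.17, Hist1h2ail1 with robust eBayes).

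Of 17 genes of cholesterol efflux and LXR targets 5 were higher at day 28 than at day 1, Apoe (2.78), Pltp (1.44), Srebf1 (0.91), Cyp27a1 (1.08) and Npc1 (0.69) (6 adjusted over the list alone; median log2 difference 0.32). Camera put the cholesterol efflux and LXR targets list at adjusted p = 0.00138, and at adjusted p = 0.169 with an estimated correlation. Sterol synthesis genes were higher in 5 of 22, Fdft1 (0.87), Fdps (1.12), Insig1 (0.57), Hmgcs1 (0.68) and Cyp51 (0.64), and Pmvk (-0.71) was lower (8 and 1 adjusted over the list alone). Camera put the sterol biosynthesis list at adjusted p = 0.00208, and at adjusted p = 0.169 with an estimated correlation. Lysosome genes were higher in 3 of 26, among them Ctsk (1.53) and Man2b1 (0.53), and Ctsl (-1.42) was lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00985, adjusted p = 0.584 with an estimated correlation), and the list missed the threshold without NM day 1 replicate 0 (adjusted p = 0.057). The lysosome list also missed the threshold with fry (adjusted p = 0.293). Scarb1, a receptor of high-density lipoprotein, was the 1 of 14 uptake genes that differed (0.96; 1 adjusted over the list alone). Camera put the scavenger receptors and lipid uptake list at adjusted p = 0.818, and at adjusted p = 0.979 with an estimated correlation. Fatty acid oxidation genes Acadvl (0.73) and Hadhb (0.61) were higher of 21 (1 adjusted over the list alone). Camera put the fatty acid oxidation list at adjusted p = 0.377, and at adjusted p = 0.804 with an estimated correlation. In lipid droplets Acsl3 (-0.82) was lower of 21 (0 adjusted over the list alone), with a median of -0.02, a mean of -0.04 and a test that pointed up. Camera put the lipid droplets, esterification and lipolysis list at adjusted p = 0.988, and at adjusted p = 0.987 with an estimated correlation. Elovl5 (0.69) was the 1 of 16 fatty acid synthesis genes that was higher (1 adjusted over the list alone; median -0.0011, mean 0.10, test upward). Camera put the fatty acid and phospholipid synthesis list at adjusted p = 0.456, and at adjusted p = 0.572 with an estimated correlation. Calls of Acsl3, Cyp27a1, Cyp51, Elovl5, Fdps, Hadhb, Hmgcs1, Insig1, Man2b1, Npc1 and Pmvk ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.197, Acsl3 without NM day 1 replicate 1). Acsl3, Apoe, Hadhb, Man2b1, Npc1 and Pmvk did not pass with isoforms tested singly, Acsl3, Cyp51, Hmgcs1, Insig1, Man2b1 and Npc1 with only the 6 libraries compared, Acsl3, Hadhb, Man2b1, Npc1 and Pmvk with a pseudocount of 0.1 or with a filter of 5 FPKM, Acsl3, Hadhb, Insig1, Man2b1 and Npc1 after quantile normalisation, Acsl3, Hadhb, Npc1 and Pmvk without a filter, Acsl3, Hadhb and Man2b1 with robust eBayes, Hadhb, Man2b1 and Npc1 after median-of-ratios scaling, Acsl3 and Man2b1 with a pseudocount of 5, Npc1 with library weights (adjusted p up to 0.113, Acsl3 after quantile normalisation).

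Among the fixed genes of lipid handling, Pparg was higher at day 28 than at day 1 (log2 fold change 0.61 ± 0.15 SE, adjusted p = 0.0192 by limma). Cd36, Msr1, Abca1, Abcg1, Nr1h3 and Cpt1a did not differ past the threshold, with log2 differences of -0.21, -0.45, 0.78, -0.13, 0.26 and -0.37 (adjusted p = 0.763, 0.094, 0.171, 0.713, 0.435 and 0.15). Nor did Nos2 (-0.51, adjusted p = 0.498) or Arg1 (-0.35, adjusted p = 0.578). Msr1 passed without NM day 28 replicate 1 (adjusted p = 0.0421), with library weights (0.0228) and after quantile normalisation (0.0461), and Abca1 without NM day 1 replicate 1 (0.03). Without NM day 1 replicate 0 or 1 or NM day 28 replicate 0 or 2, the call of Pparg ended (adjusted p up to 0.0928).

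MHC class II genes were lower at day 28 than at day 1 in 10 of 12 (11 adjusted over the list alone; median log2 difference -2.81; camera adjusted p = 3.55e-14, adjusted p = 0.0659 with an estimated correlation), with RT1-Da at 13.7 ± 7.80 against 293 ± 52.9 FPKM (SD, n = 3). Alveolar epithelial markers were lower in 12 of 16 and Napsa (0.84) was higher (13 and 1 adjusted over the list alone). Camera put the alveolar epithelium list at adjusted p = 9.46e-10, and at adjusted p = 0.126 with an estimated correlation. Monocyte markers were lower in 8 of 21 (13 adjusted over the list alone). Camera put the monocyte and recruited macrophage list at adjusted p = 2.33e-07, and at adjusted p = 0.0659 with an estimated correlation. Interferon-stimulated genes, among them Mx2 (-3.16) and Isg15 (-2.16), were lower in 7 of 26 and Ifi44 (0.88) was higher (12 and 1 adjusted over the list alone). Camera put the interferon-stimulated genes list at adjusted p = 1.67e-07, and at adjusted p = 0.0737 with an estimated correlation. Alternative activation genes, with Ccl22 (-4.25) and Ccl17 (-4.73), were lower in 8 of 21 (11 lower and 1 higher adjusted over the list alone). Camera put the alternative activation and inflammation resolution list at adjusted p = 6.78e-05, and at adjusted p = 0.0659 with an estimated correlation. Of 20 pro-inflammatory genes Ccl7 (-3.72), Cxcl10 (-2.48), Ccl5 (-1.95), Cxcl1 (-1.86) and Ccl2 (-1.66) were lower (5 adjusted over the list alone). Camera put the pro-inflammatory activation list at adjusted p = 0.00138, and at adjusted p = 0.169 with an estimated correlation. Cell cycle genes were lower in 18 of 32, as Mki67 (-1.49) and Ccna2 (-1.60), and Ccne2 (0.95) was higher (25 and 1 adjusted over the list alone). Camera put the cell cycle and proliferation list at adjusted p = 1.16e-11, and at adjusted p = 0.0659 with an estimated correlation. Calls of Ccl2, Ifi44 and Napsa ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0 or 1 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.178, Ifi44 without NM day 1 replicate 0). Ccl2 and Ifi44 did not pass with a pseudocount of 0.1 or without a filter or with a filter of 5 FPKM or with isoforms tested singly or with library weights, Cxcl1 and Ifi44 after quantile normalisation, Ccl2 with robust eBayes, Ifi44 after median-of-ratios scaling or with only the 6 libraries compared (adjusted p up to 0.0992, Ccl2 without a filter).

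In cross-link repair 2 of 13 genes were lower at day 28 than at day 1, among them Fancd2 (-1.43), and Ercc1 (0.93) was higher (6 and 1 adjusted over the list alone). Camera put the cross-link and homologous recombination repair list at adjusted p = 0.0481, and at adjusted p = 0.159 with an estimated correlation. Airway epithelial markers Krt15 (-2.44) and Cyp2f4 (-1.75) were lower of 9 (6 adjusted over the list alone). Camera put the airway epithelium list at adjusted p = 0.00339, and at adjusted p = 0.34 with an estimated correlation. T cell markers Cd8a (-2.26), Il7r (-1.52) and Cd2 (-1.56) were lower of 10 (5 adjusted over the list alone). Camera put the T cell list at adjusted p = 0.0123, and at adjusted p = 0.155 with an estimated correlation. Ccr7 (-2.58) was the 1 of 6 dendritic cell markers that was lower (4 adjusted over the list alone). Camera put the dendritic cell list at adjusted p = 0.0418, and at adjusted p = 0.159 with an estimated correlation. Endothelial markers Plvap (-2.11), Esam (-1.73) and Pecam1 (-0.74) were lower and Tie1 (1.75) higher of 6 (4 and 1 adjusted over the list alone). Camera put the endothelium list at adjusted p = 0.0434, and at adjusted p = 0.159 with an estimated correlation. The repair list missed the threshold without PBS replicate 0 or 2, NM day 1 replicate 0 or NM day 28 replicate 1 or 2 (adjusted p up to 0.073). So did the dendritic cell list without PBS replicate 0 or 2, NM day 1 replicate 1 or NM day 28 replicate 0 (0.0762). The endothelial list missed it without PBS replicate 0, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 2 (0.274). The repair list changed direction with a filter of 5 FPKM (adjusted p = 0.875). The repair list also missed the threshold with a pseudocount of 0.1, after quantile normalisation, with isoforms tested singly, with only the 6 libraries compared or with library weights (adjusted p up to 0.147), the airway list with fry (0.0514) and the T cell list after quantile normalisation (0.0792). The dendritic cell list also missed the threshold with a pseudocount of 0.1, without a filter, with a filter of 5 FPKM, after quantile normalisation or with only the 6 libraries compared (adjusted p up to 0.0673) and the endothelial list with a pseudocount of 0.1, with a pseudocount of 5, after quantile normalisation or with only the 6 libraries compared (up to 0.107). Calls of Cd2, Fancd2 and Pecam1 ended in 1 or more of the fits without NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 or 2 (adjusted p up to 0.108, Pecam1 without NM day 1 replicate 2).

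The remaining lists did not pass between day 28 and day 1. In the neutrophil list Cxcr2 (-1.70) and Lcn2 (-2.95) were lower, as was Retnlg, and Cxcr1 (1.12) higher of 11 (3 and 1 adjusted over the list alone). Camera put the neutrophil list at adjusted p = 0.0585, and at adjusted p = 0.183 with an estimated correlation. Natural killer markers Klrk1 (-3.90), Gzmm (-1.12) and Ctsw (-1.15) were lower of 6 (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0629, adjusted p = 0.169 with an estimated correlation), and Cd22 (-1.71) and Blk (-1.28) of 3 B cell markers (3 adjusted over the list alone). Profibrotic genes Tgfbi (-3.66) and Sparc (-1.73) were lower and Trem2 higher of 20 (2 and 2 adjusted over the list alone), with a median of 0.16, a mean of -0.15 and a test that pointed up. Camera put the profibrotic factors and matrix remodelling list at adjusted p = 0.988, and at adjusted p = 0.987 with an estimated correlation. In the p53 list Gadd45b (-2.05), Perp (-1.78), Phlda3 (-1.64) and Gadd45a (-0.69) were lower of 22 (4 adjusted over the list alone). Camera put the p53 and DNA damage response list at adjusted p = 0.456, and at adjusted p = 0.804 with an estimated correlation. Oxidative stress genes Gpx2 (-2.79) and Slc7a11 (-1.04) were lower, and 2 of 26 were higher, among them Srxn1 (1.05) (2 and 3 adjusted over the list alone). Camera put the NRF2 and oxidative stress response list at adjusted p = 0.415, and at adjusted p = 0.943 with an estimated correlation. In ER stress Hsp90b1 (-0.97) and Hspa5 (-0.83) were lower and Asns (0.93) higher of 20 (2 and 2 adjusted over the list alone), with a median of 0.08, a mean of -0.01 and a test that pointed up. Camera put the ER stress and integrated stress response list at adjusted p = 0.959, and at adjusted p = 0.987 with an estimated correlation. Calls of Asns, Blk, Ctsw, Gadd45a, Gzmm, Hspa5, Lcn2, Perp, Phlda3, Retnlg, Slc7a11, Sparc, Srxn1 and Trem2 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.176, Slc7a11 without NM day 1 replicate 1). Blk, Ctsw, Gzmm and Slc7a11 did not pass after quantile normalisation, Ctsw, Retnlg, Slc7a11 and Srxn1 with a pseudocount of 0.1, Ctsw, Lcn2, Srxn1 and Trem2 without a filter, Ctsw, Slc7a11, Srxn1 and Trem2 with isoforms tested singly, Ctsw, Slc7a11 and Srxn1 with only the 6 libraries compared, Lcn2 and Trem2 with robust eBayes (adjusted p up to 0.203, Gzmm after quantile normalisation).

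Resident macrophage markers Pparg (0.61) and Siglec1 (0.93) were higher of 14 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.826, adjusted p = 0.979 with an estimated correlation), and Treml1 (1.92) of 4 platelet markers (2 adjusted over the list alone). Limma called 0 of 17 glycolysis, 0 of 5 erythroid, 0 of 2 eosinophil and mast cell and 0 of 2 fibroblast and smooth muscle genes, with 2, 0, 1 and 2 at an unadjusted p under 0.05. Adjusted over each list alone, 0, 0, 1 lower and 2 higher passed, and the glycolysis and erythroid lists did not (camera adjusted p = 0.826 and 0.988, adjusted p = 0.987 and 0.987 with an estimated correlation). Calls of Pparg, Siglec1 and Treml1 ended in 1 or more of the fits without NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 or 2 (adjusted p up to 0.14, Siglec1 without NM day 1 replicate 0). Siglec1 and Treml1 did not pass without a filter, Siglec1 with isoforms tested singly (adjusted p up to 0.0659, Siglec1 without a filter).

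**Figure D3:**
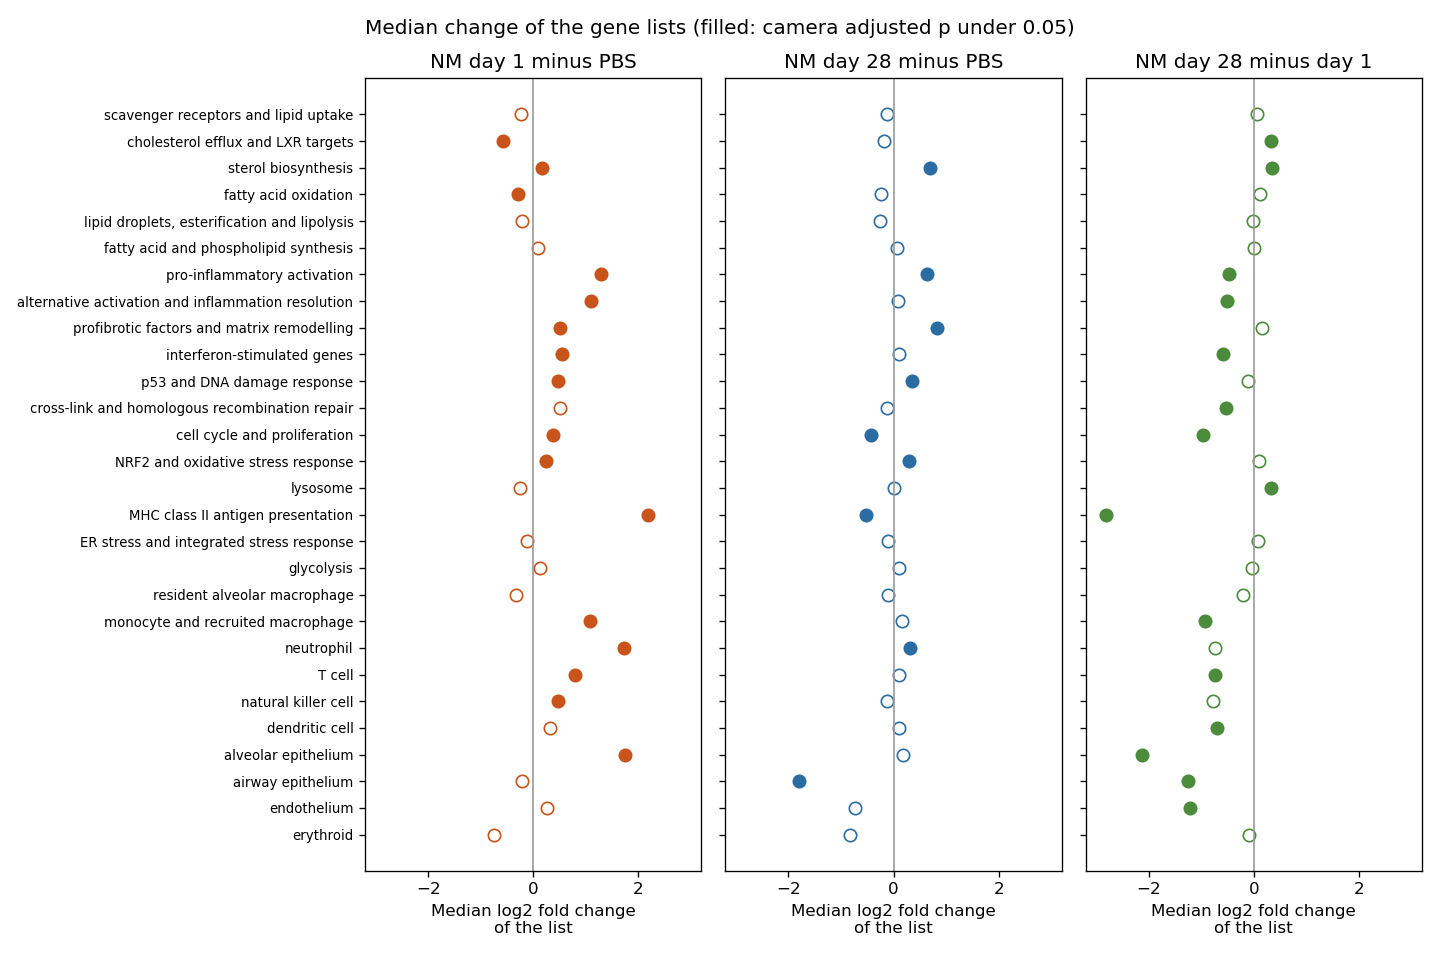
Median log2 fold change (horizontal axes) of the 28 gene lists tested, for NM day 1 minus PBS, NM day 28 minus PBS and NM day 28 minus day 1. Filled points passed camera with its preset correlation (16, 9 and 15 lists), of which 3, 0 and 0 also passed with the correlation estimated. The MHC class II list lies at 2.17, -0.52 and -2.81.

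The responses at the 2 days were also set against each other. Of the genes called in both, 124 were higher at both days, among them Apoe, S100a9, Spp1, Mmp12 and Cdkn1a, 97 were lower at both, among them Abcg1 and Cidec, and 11 went in opposite directions. Independent lists would share 16.0 and 18.0 genes. Both comparisons used the same 3 PBS libraries, and 100 simulations of unchanged groups gave a mean of 0 genes higher and 0.01 lower in both. Almost no gene is called in unchanged groups, so these simulated counts lie near 0 by construction and do not measure what shared controls add to shared calls. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.44 and Spearman's rho 0.40, against simulated means of 0.50 and 0.47. The covariance was 0.143, against 0.0406 simulated. The same sign was seen in 65.1% of genes, against 66.7% simulated. With 3 PBS libraries the controls could not be split with 2 on each side, so part of the shared calls may come from the shared controls. Genes higher in both numbered 69 without PBS replicate 1 and 69 without NM day 1 replicate 0. Those lower in both numbered 37 and 10 without PBS replicate 0 and 1, 14, 51 and 48 without NM day 1 replicate 0, 1 and 2, and 46 without NM day 28 replicate 2.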

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

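The tests of the surfactant, MHC class II and neutrophil patterns below, and of depth and other cells for the number of transcripts detected, were chosen after results were seen. The receptor background and the splits of libraries were set before the data were examined. A difference between groups, tested between the 2 NM groups, picked out 15 gene lists, of which 0 stayed past the threshold with an estimated correlation (lowest adjusted p = 0.0659 with an estimated correlation). Their median log2 differences of day 28 minus day 1 were 0.323 (cholesterol efflux and LXR targets), 0.3415 (sterol biosynthesis), 0.3195 (lysosome), -0.4675 (pro-inflammatory activation), -0.5029 (alternative activation), -0.5871 (interferon-stimulated genes), -0.5194 (cross-link repair), -0.9581 (cell cycle), -2.806 (MHC class II), -0.9313 (monocyte), -0.7459 (T cell), -0.698 (dendritic cell), -2.1306 (alveolar epithelium), -1.2592 (airway epithelium) and -1.216 (endothelium).

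The same test picked out 11 genes called in opposite directions at the 2 days. Higher at day 28 and lower at day 1 (log2 fold changes at days 1 and 28 against PBS) were Acd (-0.65 and 0.68, difference 1.3282), Enpp1 (-1.09 and 1.16, difference 2.2488), Isyna1 (-0.76 and 0.57, difference 1.332), Plcd1 (-0.55 and 0.72, difference 1.2736), Slc22a18 (-1.45 and 0.73, difference 2.1728). Lower at day 28 and higher at day 1 were Anp32e (0.76 and -0.96, difference -1.7176), Aqp5 (1.17 and -2.36, difference -3.5268), Dut (0.81 and -0.65, difference -1.4623), Msln (1.45 and -1.73, difference -3.1868), S100a16 (1.11 and -1.14, difference -2.2579), Tspan1 (1.15 and -1.55, difference -2.6981). At day 1 against PBS: Calls of Acd, Anp32e, Aqp5, Dut, Enpp1, Isyna1, Msln, Plcd1, S100a16 and Tspan1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0 (adjusted p up to 0.191, S100a16 without NM day 1 replicate 0). Acd, Aqp5, Enpp1, Msln, S100a16 and Tspan1 did not pass without a filter, Acd, Plcd1, S100a16 and Tspan1 after quantile normalisation, Acd, Aqp5, S100a16 and Tspan1 with isoforms tested singly, Aqp5, S100a16 and Tspan1 with a pseudocount of 0.1, S100a16 and Tspan1 with a filter of 5 FPKM, Acd after median-of-ratios scaling, S100a16 with library weights (adjusted p up to 0.335, Tspan1 with a pseudocount of 0.1). At day 28 against PBS: Calls of Acd, Dut, Enpp1, Isyna1, Msln, S100a16, Slc22a18 and Tspan1 ended in 1 or more of the fits without PBS replicate 0, 1 or 2, NM day 1 replicate 0, 1 or 2 or NM day 28 replicate 0, 1 or 2 (adjusted p up to 0.2, S100a16 without PBS replicate 1). Acd, Dut, Enpp1, Isyna1, Msln and S100a16 did not pass without a filter, Acd, Dut, Isyna1 and S100a16 with isoforms tested singly or with only the 6 libraries compared, Dut and S100a16 after median-of-ratios scaling, Isyna1 and S100a16 with a pseudocount of 5 or with a filter of 5 FPKM, Dut after quantile normalisation, Isyna1 with robust eBayes (adjusted p up to 0.103, S100a16 without a filter).

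Of 16 alveolar epithelial genes 11 rose at day 1, Sftpb, Sftpc and Sftpa1 among them, and of 12 MHC class II genes 8, but both list calls were lost (adjusted p = 0.0935 and 0.0619 with an estimated correlation). Alveolar epithelial cells among the day 1 cells are consistent with the surfactant rise, as 8 of 13 other alveolar epithelial markers also rose. For the 8 MHC class II genes the same source was not decided. Between the day 1 libraries with the most and the least Sftpc, these differed by a median of -0.2267 (range -0.52 to 0.19), against 1.937 for Sftpc, Sftpb and Sftpa1. Induction in macrophages and antigen-presenting cells that entered the lung were not told apart.

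Of 11 neutrophil genes 5 were higher and 1 lower than in PBS at day 1 and 4 higher at day 28, and both list calls were lost (adjusted p = 0.0619 and 0.286 with an estimated correlation). Neutrophils among the collected cells remain open, with 4 of 8 markers under 30 FPKM in PBS called higher at day 28 and 5 at day 1. Monocytes of the day 1 kind as the source at day 28 also remain open. The 10 monocyte genes called higher at day 1 lay at a median of -2.5237 at day 28 against day 1 (range -4.75 to -0.70), but 3 of them were also called higher at day 28. The 4 neutrophil genes called higher at both days lay at a median of -0.7638 (range -1.70 to -0.40), so the ranges overlapped.

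Fewer transcripts were detected in the day 28 libraries. PBS and day 1 libraries listed 12112 to 12516 transcripts at depths of 1 to 2.58, 12177 at the deepest. Among these libraries the number did not rise steadily with depth, but lower depth at day 28 remains open. NM day 1 replicate 0 (depth 1) listed 773 more than the highest day 28 library, but it alone was so shallow (day 28: 1.04 to 1.12). A background of genomic DNA or stray reads in the other libraries remains open. The share of olfactory and vomeronasal receptor transcripts above 0 was 1.1333 times as high in the lowest PBS or day 1 library as in the highest day 28 library. Fewer cells of other types also remain open, with 3 of 7 lists of other cells under -0.5 at day 28.

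All 10 splits of the 6 libraries of each comparison were refitted. The real grouping gave 975, 696 and 1150 called genes and the highest other split 0 in each comparison, so 1 split of 10 reached the real count. With 10 splits the share cannot fall under 0.05.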

How the results depend on the processing

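Without 1 library, genes at day 1 numbered 181 to 658 higher and 55 to 721 lower, at day 28 154 to 368 and 120 to 426, and at day 28 against day 1 214 to 630 and 300 to 776. Lists at day 1 numbered 12 to 14 higher and 2 to 5 lower, at day 28 5 to 7 and 2 to 4, and at day 28 against day 1 2 to 4 and 9 to 13. Genes higher in both numbered 69 to 162 and lower in both 10 to 120, and r ran from 0.408 to 0.480. Of the called genes picked by the rule, 38 of 57, 39 of 55 and 28 of 38 stayed past the threshold without each library, and of the lists 12 of 16, 7 of 9 and 11 of 15. With a filter of 5 FPKM, 324 genes were higher at day 1 and 408 lower at day 28 against day 1, with fewer genes tested. Under that filter the cross-link repair list between the NM groups changed sign (0.126 as signed -log10 p, adjusted p = 0.875), and the cause was not tested. Library weights gave 742 lower at day 1, 498 higher and 657 lower at day 28, 911 higher and 1093 lower at day 28 against day 1, and 191 lower in both, and the cause was not tested. With only the 6 libraries compared, 230 genes were lower at day 28. Lists lower at day 1 numbered 5 without a filter and 1 after quantile normalisation, and genes lower in both 60 after quantile normalisation and 63 with isoforms tested singly. Of 40 list calls, 34 stayed past the threshold after quantile normalisation, 34 with fry, 36 with only the 6 libraries compared, 37 with library weights and 37 with a pseudocount of 0.1. With the correlation estimated, 3 lists were higher and 0 lower at day 1, 0 and 0 at day 28, and 0 and 0 between the NM groups. Without read counts, the precision of low values is not known.

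A replicate block, with the replicate number as a factor, gave 481 higher and 347 lower at day 1, 278 and 348 at day 28, and 411 and 642 between the NM groups. Among genes the rule picked for the same comparison, Nr1h3 and Pparg at day 1, Ncr3 and Slc27a4 at day 28, and Acsl3 and Hadhb between the NM groups then missed the threshold. So did 10, 10 and 9 calls of other list members and of genes called in opposite directions at day 1, at day 28 and between the NM groups, among them Acads at day 1, Pltp and Pla2g15 at day 28, and Ccl2, Insig1 and Slc7a11 between the NM groups. No list call ended. Deviations of libraries with the same number correlated from -0.104 to 0.196 over 9 pairs, 3 of them over 0.1, and 4 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs.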

Other observations

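Families of genes defined by symbol after results were seen were tested with camera in limma. Of 19 chemokines 13 rose at day 1 (median log2 fold change 1.94, adjusted p = 5.61e-15, adjusted p = 0.0078 with an estimated correlation) and 4 at day 28 (adjusted p = 0.00288, adjusted p = 0.185 with an estimated correlation). Between the NM groups 11 were lower (adjusted p = 3.00e-07, adjusted p = 0.0521 with an estimated correlation). Of 19 C-type lectins, receptors that bind sugars, 6 rose at day 1 (adjusted p = 7.49e-06, adjusted p = 0.00821 with an estimated correlation), and 7 rose and 1 fell at day 28 (adjusted p = 0.000392, adjusted p = 0.0361 with an estimated correlation).

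Of 8 keratins, filament proteins of epithelia, 1 rose at day 1 (adjusted p = 0.00648, adjusted p = 0.515 with an estimated correlation) and 3 fell at day 28 (adjusted p = 0.00366, adjusted p = 0.458 with an estimated correlation). Between the NM groups 7 were lower at day 28 (adjusted p = 6.99e-07, adjusted p = 0.162 with an estimated correlation). Of 78 ribosomal protein genes 67 had negative log2 fold changes at day 1, with a median of -0.32, and limma called 0 (adjusted p = 0.00037, adjusted p = 0.89 with an estimated correlation). Their median was -0.29 after median-of-ratios scaling and -0.01 after quantile normalisation.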
